A study of Mus musculus with 2 samples.

How the data were processed

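Total RNA after ribosomal RNA depletion was measured by sequencing in the nucleoplasmic fraction of mouse macrophages in 2 libraries of 1 group, per the labels. Other label fields call the same fraction nucleus or nuclear, so whether chromatin-bound RNA was included is not settled, and this bears on the levels of Malat1, Neat1 and retained intron transcripts. Replicate numbers came from the labels, which give separate biosamples of 1 donor identifier. Whether the cultures came from separate animals was not stated, so the spread between libraries may be partly technical. The labels give a library size range of 250 to 400 without a unit.

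The authors deposited, for each library, a gene table, a transcript table in the same format and a second transcript table. Per the file headers and the text files deposited beside them, expected counts and TPM in the gene table came from transcriptome alignments to mm10 with GENCODE annotation M21, and the second table came from the reads and the same annotation. The programs were not given in the sources used here; the column names are those that RSEM writes for the gene tables and that kallisto writes for the second tables, which are called the second quantification. Expected counts, as deposited by the authors, are estimates that need not be whole, and were rounded before use in edgeR and DESeq2. TPM, as deposited by the authors, is scaled to the sum over all entries of a table. The bounds of the deposited TPM intervals, a signal that is never negative, were used for Ptgs2 and Fosl1. These bounds surround the deposited posterior mean and can leave out the TPM itself. Strand handling was not given in the sources used here, so genes overlapping on opposite strands (such as Malat1 and Gm37376, Junb and Prdx2, or Jun and Junos) are uncertain.

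All 55536 genes of the annotation were in the tables. Entries that name no annotated gene were left out of library sizes and of all results: 26248 numeric identifiers, 96 spike-in controls with 0 counts and 1 phiX entry. They held 1.18% of counts in replicate 1 and 0.405% in replicate 2, almost all phiX. The remaining expected counts were 19153465 and 11622346. A count of 0 was given the upper limit of 3 counts, 0.157 and 0.258 CPM, converted to TPM with the gene's effective length. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

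Detection required 1 TPM in both libraries. Pearson's r was taken over genes with a mean of 1 TPM on log2(TPM + 1). The coefficient of variation is the square root of edgeR's common dispersion (version 4.0.16, R 4.3.3) after TMM scaling, with an intercept-only design and genes with at least 10 counts in both libraries. Genes more than 2-fold apart were counted on TMM-scaled counts with a pseudocount of 1 and a mean of at least 50 counts. With 1 library on each side no p-value was computed. A list's median difference between libraries was set against 10000 random lists drawn with replacement from 20 bins of mean expression, after centring on the median gene, which stood at 0.10. Retained intron transcripts were taken from the annotation. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, bedtools 2.31.1 and DESeq2 1.42.0.

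Before the data were examined, 26 gene lists were fixed: immediate early, NF-kB family and feedback, early inflammatory, late response, interferon-stimulated, TLR4 pathway, macrophage identity, nuclear long noncoding RNA, small noncoding RNA of ribonucleoproteins, snoRNA host, mitochondrially encoded, cytosolic ribosomal protein, replication-dependent histone, spliceosome and nuclear speckle protein, housekeeping, heat shock and stress, proliferation, and markers of neutrophils, B cells, T and NK cells, erythroid cells, fibroblasts, dendritic cells, mast cells, megakaryocytes and endothelium. Of their members, 4 matched no symbol (Norad, Snhg4, Snhg7 and Snhg16). Symbols with more than 1 identifier, such as Rmrp, were summed in lists. Named genes were fixed by rule: the 10 highest by mean TPM; the 4 highest and 2 lowest members of each list and, in longer lists, the one nearest the median, with any member allowed for the 5 response lists; the 5 genes farthest apart between libraries in each direction; the 5 most abundant retained intron transcripts; and the 5 genes farthest apart between the quantifications in each direction. A gene that this rule allows is not reported here. Alternatives fixed likewise were detection at 0.1 or 5 TPM or by counts, pseudocounts and filters, DESeq2 size factors and dispersions, posterior mean TPM, the second quantification summed per gene, TPM rescaled without mitochondrial genes and the 10 highest genes, and each library alone. Shares of expected counts, and the share of the same 10 highest genes under other units, were added after seeing the data. Genes apart between the quantifications were ranked among those with a mean of at least 10 TPM in the first.

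The procedure was tested on simulated libraries built from the real means and totals. With a simulated coefficient of variation of 15% and no gene changed, 14.8% was recovered. For this 55536 genes were simulated, and those with at least 10 counts in both libraries entered the estimate. Of 200 genes changed 4-fold, 99.5% passed the 2-fold limit, as did 0.403% of 11408 unchanged genes. Those changed genes raised the estimated coefficient of variation to 18.9%. The list test used independent random normal values in place of the simulated ratios, so it did not cover lists whose members vary together. In it, a list of 30 genes shifted by 0.5 lay at the 99.99th percentile, and 6.5% of 200 unshifted lists lay outside the central 95%.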

Results

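RNA of a nuclear fraction, which the labels call nucleoplasmic in one field and nucleus in another, was profiled from mouse bone marrow derived macrophages (strain C57BL/6J) that had received 100 ng/ml Lipid A, the Toll-like receptor 4 ligand of bacterial lipopolysaccharide, for 10 min. Ribosomal RNA was depleted and the remaining total RNA was sequenced. The labels place both libraries in 1 group as biological replicates 1 and 2, so levels at 1 time are described and the libraries are compared with each other. Cells without Lipid A and other times were not analysed here, and no level below is a measure of induction. Replicate 1 held 19153465 and replicate 2 held 11622346 expected counts on annotated genes. All values are mean ± SD with n = 2 unless a library is named, and coordinates are those of mm10 with GENCODE annotation M21.

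On the TPM scale, which divides counts by effective length, short structural RNAs had the highest levels. The small nuclear, small nucleolar, ribozyme and miscellaneous RNA types together held 59.7 ± 1.35% of TPM but 4.78 ± 0.151% of expected counts, and Malat1 had more counts than Rn7sk (1919770 against 424835 in replicate 1). Rn7sk, the RNA that holds the elongation factor P-TEFb inactive, had the highest level in the gene tables, at 185060 ± 20651 TPM (chromosome 9, 78175303 to 78175633). Rmrp, the RNA of the RNase MRP complex, followed at 65499 ± 15900 TPM, and Rpph1, the RNA of RNase P, stood at 40142 ± 3026 TPM. Rn7s1 and Rn7s2, RNA genes of the signal recognition particle, had 40899 ± 29149 TPM each; their annotated sequences are identical, so the level of either one is uncertain. The small nuclear RNA Gm22513 (28029 ± 15258 TPM), the nuclear long noncoding RNA Malat1 (25175 ± 7442 TPM), the small nucleolar RNA Gm22988 (18289 ± 12889 TPM), mt-Atp8 (15752 ± 7963 TPM) and mt-Co1 (14308 ± 1655 TPM) completed the 10 highest genes. Gm22988 lies in Eif4a1, mt-Atp8 overlaps mt-Atp6 on the same strand, and Rmrp overlaps an annotated gene of the same name, so reads there are shared.

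The 10 highest genes held 47.5 ± 0.908% of TPM. Protein-coding genes held 30.2 ± 1.04% of TPM, whereas they held 77.0 ± 1.02% of expected counts, because the short RNAs have small effective lengths. The effective length of Gm22988 was 2.65 nucleotides in replicate 1, and 547 counts there gave 9175 TPM. Long intergenic RNAs, with Malat1 among them, held 4.38 ± 0.783% of TPM and 13.4 ± 0.54% of counts. Mitochondrially encoded genes, which mark organelle RNA, held 6.32 ± 1.01% of TPM, and all 15 were detected. Reads shared with pseudogenes of mitochondrial sequence, such as Gm10222 (5935 TPM), make that share uncertain. By the second quantification the same 10 genes held 16.8% of TPM, with Rn7sk at 73376 TPM below 5 genes listed at 0 in the gene tables, and mitochondrially encoded genes held 3.75%.

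**Figure D1:**
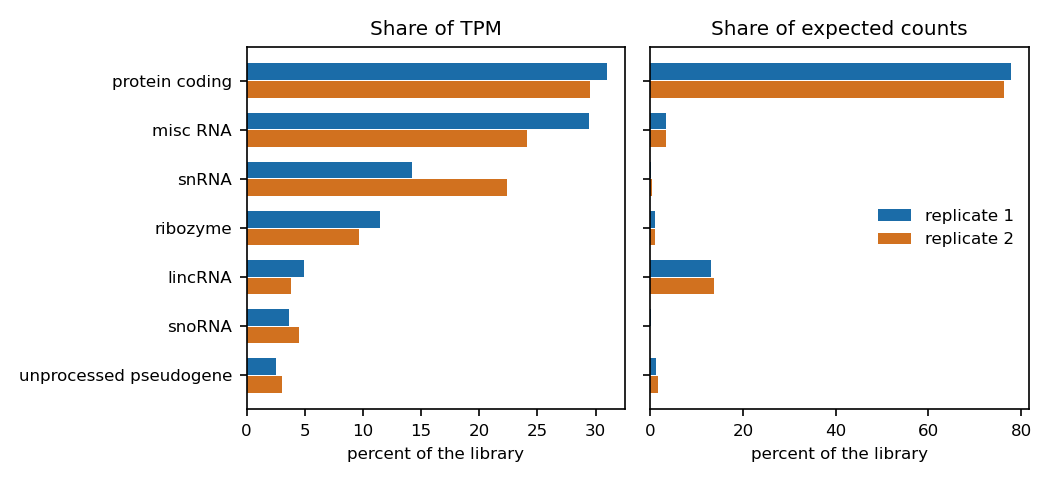
Share of each library's annotated-gene signal taken by the 7 gene types with the highest mean share of TPM, in percent of TPM (left) and percent of expected counts (right); bars are single libraries. Protein-coding genes held 31.0% and 29.5% of TPM but 77.8% and 76.3% of counts in replicates 1 and 2.

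At 1 TPM or more in both libraries, 13116 of 55536 annotated genes were detected. These comprised 10123 of 22028 protein-coding genes and 1201 of 10155 long noncoding genes. Across the 13951 genes with a mean of at least 1 TPM, Pearson's r between the libraries was 0.93 on log2(TPM + 1); genes are not independent replicates, so no p-value is given. The biological coefficient of variation, estimated by edgeR from 14547 genes, was 16.2%, and the square root of the median of DESeq2 gene-wise dispersions over the same genes was 5.36%. The chi-square per degree of freedom over those genes was 32.2, where counting error alone would give about 1. Separate libraries usually exceed that, and the value does not separate biological spread from that of library preparation.

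Immediate early genes, which cells transcribe without new protein synthesis, were present in nucleoplasmic RNA. Of 30 members, 27 were detected in both libraries, with a list median of 22.5 ± 14.8 TPM. The highest were Mcl1, a survival factor of the Bcl-2 family (246 ± 34.9 TPM), Zfp36, which destabilises AU-rich mRNAs (180 ± 102 TPM), Junb (119 ± 85.8 TPM) and Fos (118 ± 80.2 TPM). Fos, a subunit of the transcription factor AP-1, lies on chromosome 12 from 85473890 to 85477273. Egr1, a zinc finger transcription factor, stood at 24.7 ± 25.8 TPM, and its level was 42.9 TPM in replicate 1 and 6.43 TPM in replicate 2. Lower members were Egr2 (5.32 ± 2.91 TPM), Egr3 (4.29 ± 1.31 TPM) and Myc (2.44 ± 0.912 TPM). Klf4 (0.6 ± 0.0849 TPM) and Ccn1 (0.065 ± 0.0636 TPM) stayed under 1 TPM. Fosl1 had 0 counts in both libraries, which allows up to 0.197 TPM in replicate 1 and 0.299 TPM in replicate 2. Its deposited intervals, which surround the posterior mean, reached 1.21 and 1.69 TPM.

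All 16 members of the NF-kB list, the transcription factor family and its feedback inhibitors, were detected in both libraries. Nfkbia, which encodes the inhibitor IκBα, had the highest level at 43.8 ± 37.3 TPM (chromosome 12, 55489410 to 55492647). Nfkb1 stood at 38.3 ± 6.23 TPM, Birc3 at 30.3 ± 12.7 TPM and Tnfaip3, which encodes the deubiquitinase A20, at 24.2 ± 10.8 TPM. The subunits Rel (16.6 ± 1.22 TPM) and Rela (14.0 ± 2.53 TPM) differed less between the libraries than Nfkbia. Traf1 was lowest, at 4.32 ± 0.99 TPM.

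Of 20 early inflammatory genes, 19 were detected in both libraries and Ptgs2, which encodes cyclooxygenase-2, in replicate 1 only (2.69 TPM against 0.82 TPM in replicate 2). The deposited intervals of Ptgs2 were 2.32 to 3.67 TPM and 0.59 to 2.11 TPM. By the second quantification Ptgs2 stood at 5.17 and 2.73 TPM in replicates 1 and 2, and all 20 members were detected in both libraries. The chemokine genes Ccl3 (88.2 ± 26.0 TPM) and Ccl4 (71.8 ± 42.0 TPM), neighbours on chromosome 11, were among the highest, with Plk2 (73.5 ± 13.0 TPM) and Irf1 (60.8 ± 30.8 TPM). Tnf, the gene of tumour necrosis factor, stood at 47.2 ± 41.7 TPM (chromosome 17, 35199381 to 35202007), with 2432 and 365 expected counts in replicates 1 and 2. Il1b (18.8 ± 18.4 TPM), Cxcl1 (6.90 ± 6.99 TPM) and Socs3 (5.92 ± 6.07 TPM) had an SD close to or above their mean.

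Genes of the late response, whose transcription in macrophages usually follows new protein synthesis or chromatin remodelling, were mostly low. Of 20 members, 6 were detected in both libraries and 14 in neither. Ebi3 (11.1 ± 2.79 TPM), Il10 (6.31 ± 3.21 TPM), Acod1 (5.59 ± 2.91 TPM), Saa3 (5.37 ± 2.32 TPM), Cd40 (3.83 ± 2.79 TPM) and Il27 (1.33 ± 0.184 TPM) were the detected members. Il6 stood at 0.21 ± 0.156 TPM, from 11 and 3 counts. Nos2, which encodes inducible nitric oxide synthase, stood at 0.085 ± 0.00707 TPM and Il12b at 0.635 ± 0.417 TPM. Ifnb1 had 10 counts in replicate 1 and 0 in replicate 2, where up to 0.387 TPM remains possible. Il12a had 0 counts in both. With detection at 0.1 TPM, 12 of the 20 late members were present, and with 5 TPM only Ebi3 was.

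**Figure D2:**
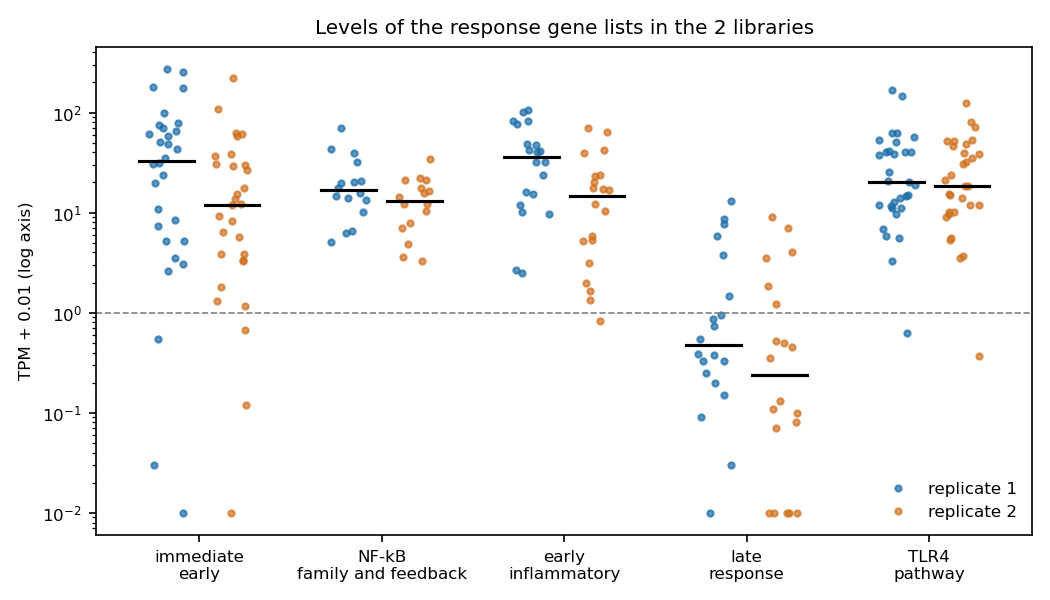
TPM of each member of 5 response lists in replicate 1 (blue) and replicate 2 (orange), on a log axis after adding 0.01; black bars are medians over members and the dashed line marks 1 TPM. The medians of the immediate early list were 33.0 and 12.0 TPM, and those of the late list 0.46 and 0.23 TPM.

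The receptor pathway that senses Lipid A was expressed, with 30 of 31 members detected in both libraries. Tlr4 stood at 34.9 ± 4.42 TPM, its co-receptor gene Ly96 at 13.1 ± 3.05 TPM and the adaptor gene Myd88 at 12.1 ± 3.42 TPM. The kinase genes Ikbke (135 ± 13.8 TPM) and Tbk1 (71.4 ± 11.8 TPM) were among the highest, and Cd14 stood at 120 ± 68.2 TPM. Lbp, made mainly by liver, was the member under 1 TPM (0.485 ± 0.177 TPM), but it stood at 1.13 and 1.4 TPM by the second quantification. All 28 interferon-stimulated genes were detected, with a list median of 26.9 ± 3.62 TPM. Oasl2 (176 ± 5.07 TPM), Oas2 (133 ± 11.1 TPM) and Stat2 (102 ± 0.467 TPM) were the highest, and Isg20 the lowest (1.90 ± 0.757 TPM).

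Macrophage genes were abundant, with 30 of 31 identity members detected and a list median of 164 ± 47.0 TPM. Gpnmb (2701 ± 459 TPM), the cathepsin genes Ctsd (1926 ± 712 TPM) and Ctsb (1842 ± 681 TPM) and the lysozyme gene Lyz2 (1762 ± 773 TPM) were the highest. Lyz1, a near-identical relative of Lyz2, stood at 0.88 ± 0.156 TPM, and reads shared between the lysozyme genes make its level uncertain. Nuclear RNAs were likewise prominent. Neat1, the architectural RNA of paraspeckles, stood at 1647 ± 190 TPM and Xist at 329 ± 2.55 TPM. Meg3 was listed at 0 counts. Of the nuclear long noncoding RNAs, 11 of 14 matched members were detected, as were all 11 matched snoRNA host genes, led by Gas5 (83.7 ± 1.95 TPM), and 8 of 10 small RNAs of ribonucleoproteins, while Rny1 and Rny3 were listed at 0 without a usable effective length, so that no level can be given from the gene tables. They stood at 2.56 and 9.55 TPM by the second quantification. All 28 genes of spliceosome and nuclear speckle proteins were detected, with a median of 153 ± 8.87 TPM. Ddx5 (543 ± 18.2 TPM) and Hnrnpa2b1 (479 ± 9.82 TPM) led that list.

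Transcripts annotated as retained intron held 6.03 ± 0.144% of transcript TPM, and 19.7 ± 0.224% when only transcripts of protein-coding genes were counted. Intronic reads were not counted apart, so reads of unspliced RNA assigned to such models may be included. The share in expected counts was not computed. The 5 most abundant came from H2-K1 (542 ± 175 TPM), Rsrp1 (421 ± 60.1 TPM), Lilrb4a (344 ± 54.5 TPM), Gpnmb (329 ± 185 TPM) and Sat1 (318 ± 30.2 TPM). The Rsrp1 transcript held 72.5% of its gene's TPM, and the Gpnmb transcript 12.2%. Sat1 encodes the polyamine-degrading enzyme SSAT.

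Markers of other blood and tissue cells were low with a few exceptions. In the gene tables none of the 10 fibroblast and stromal genes and none of the 8 mast cell and basophil genes reached 1 TPM in either library. By the second quantification the stromal marker Thy1, named after its values were seen, stood at 4.07 and 8.71 TPM and Cd3d at 2.53 and 10.1 TPM in replicates 1 and 2, while Gp1ba and S100a8 were under 1 TPM in at least 1 library. Thy1 is one of 466 protein-coding genes at 1 TPM or more there and under 0.1 TPM in the gene tables, which are weighed below. Its value is therefore no evidence of stromal cells. Of 11 T and NK cell genes, Cd4 alone was detected (24.5 ± 1.6 TPM), with Cd3d at 0.05 ± 0.0707 TPM, and of 8 B cell genes Ighm alone (4.57 ± 0.141 TPM). Vwf, the gene of von Willebrand factor, stood at 38.5 ± 0.912 TPM and Kdr at 4.93 ± 0.82 TPM, while Cdh5 (0.055 ± 0.0495 TPM) and the other 3 endothelial members stayed under 1 TPM. Pf4, a platelet chemokine gene, stood at 39.7 ± 9.09 TPM and Gp1ba at 1.10 ± 0.0707 TPM, the 2 detected members of 6 on the megakaryocyte list. Of 9 erythroid genes, Alas2 (4.47 TPM in replicate 1 and 5.53 TPM in replicate 2) and Epor (1.90 ± 0.636 TPM) were detected, and Hbb-bs had 0 counts. Alas2 overlaps Apex2 on the opposite strand, so its level is uncertain. Of 12 neutrophil genes, Mmp8 (3.14 ± 0.403 TPM) and S100a8 (1.64 ± 0.156 TPM, from 9 and 7 counts) were detected in both libraries, and S100a9 and Ngp in 1 library each. The detected 5 of 12 dendritic cell genes included the antigen presentation genes Cd74 (58.9 ± 27.6 TPM), H2-Ab1 (25.4 ± 8.12 TPM) and H2-Aa (24.9 ± 11.6 TPM), which activated macrophages also express. The proliferation list was low, with 16 of 21 detected and a median of 1.99 ± 0.0354 TPM, and its highest member was Pcna (28.6 ± 6.43 TPM). Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were detected for 45 of 65 members, led by Hist3h2a (40.6 ± 14.2 TPM). Hist3h2a overlaps Trim17 on the same strand, so its level is uncertain. Heat shock and stress genes were led by Hspa8 (169 ± 70.6 TPM) and Hspa5 (159 ± 79.4 TPM), with 11 of 15 detected and Hspa1b at 0.32 ± 0.099 TPM. All 14 housekeeping genes, led by Actb (741 ± 58.8 TPM), and all 36 cytosolic ribosomal protein genes, led by Rpl10 (141 ± 52.3 TPM), were detected.

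The 2 libraries were then compared, to see which genes carried the spread between replicates. They had been made from different amounts of RNA, 1 µg for replicate 1 and 500 ng for replicate 2, and these values compare the libraries and not conditions. Early inflammatory and immediate early mRNAs were higher in replicate 1. The median log2(TPM + 1) difference, taken relative to the median gene, was 1.17 for the early inflammatory list, with 20 of 20 members higher in replicate 1, and 0.88 for the immediate early list, with 27 of 27 higher. Both medians lay above all 10000 random lists of the same size matched on expression, whose central 95% ran from -0.16 to 0.17 and from -0.15 to 0.15. Random lists are drawn gene by gene, whereas members of a list can vary together, so these ranges describe the libraries and are no test. Ribosomal protein, histone and housekeeping lists also lay above their random ranges. The difference was 2.46 for Egr1, 2.16 for Il1b, 1.95 for Tnf, 1.92 for Btg2 and 1.85 for Nfkbia. It was 0.19 for Mcl1 and 0.26 for Plk2.

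In the gene tables other lists moved less. By the second quantification the early inflammatory list stood at 1.05, while the immediate early list, at 0.72, lay below the small RNAs of ribonucleoproteins, at 0.82. Cytosolic ribosomal protein mRNAs had a median difference of 0.64 with 35 of 36 members higher in replicate 1, among them Rplp1 (1.15) and Rpl10 (0.67), while Rps24 stood at -0.02. Histone genes (0.57, 44 of 49), macrophage identity genes (0.43, 26 of 30), the late response list (0.60, 5 of 6) and the dendritic cell list (0.54, 5 of 5) also lay above the central 95% of their random lists. So did the housekeeping (0.29, 12 of 14), interferon-stimulated (0.27, 20 of 28), NF-kB (0.26, 13 of 16) and heat shock (0.24, 10 of 12) lists. By the second quantification the differences of the macrophage identity and interferon-stimulated lists were smaller, at 0.175 and 0.181, and lay above their random ranges. There the late response, housekeeping and heat shock lists lay inside their random ranges, and the heat shock list did so under 2 other settings. When members under 1 TPM were kept, the late response difference was 0.205 over 19 members and the dendritic cell difference turned to -0.0815. Actb, in the housekeeping list, had a difference of 0.06. Genes of the TLR4 pathway had a median difference of 0.00 with 15 higher and 15 lower. Spliceosome and speckle protein genes (-0.21, 26 of 28 lower) and mitochondrially encoded genes (-0.44, 10 of 15 lower) lay below that range. Within the mitochondrial list mt-Atp8 had -1.18, while mt-Co3 (2.40) and mt-Nd4l (1.39), both named after their values were seen, and mt-Co2 (1.18) went the other way. Pseudogenes of mitochondrial sequence, such as Gm10222, held 5935 TPM in the gene tables and 0 by the second quantification. How reads shared with them were assigned was not examined, so differences of single mitochondrial genes are uncertain. The list median was -0.54 in the second quantification, also below its random range. The proliferation list (-0.17), the nuclear long noncoding RNAs (-0.07), the small RNAs of ribonucleoproteins (0.20, but 0.82 and above the range by the second quantification) and the snoRNA hosts (0.08) lay inside the central 95%, as did the neutrophil (0.10), megakaryocyte (0.16), endothelial (0.06) and erythroid (-0.00) lists, which rested on 3, 2, 2 and 2 members. In 4 lists (B cell, T and NK cell, fibroblast and stromal, mast cell and basophil) fewer than 2 members had a mean of 1 TPM, and no difference was computed.

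**Figure D3:**
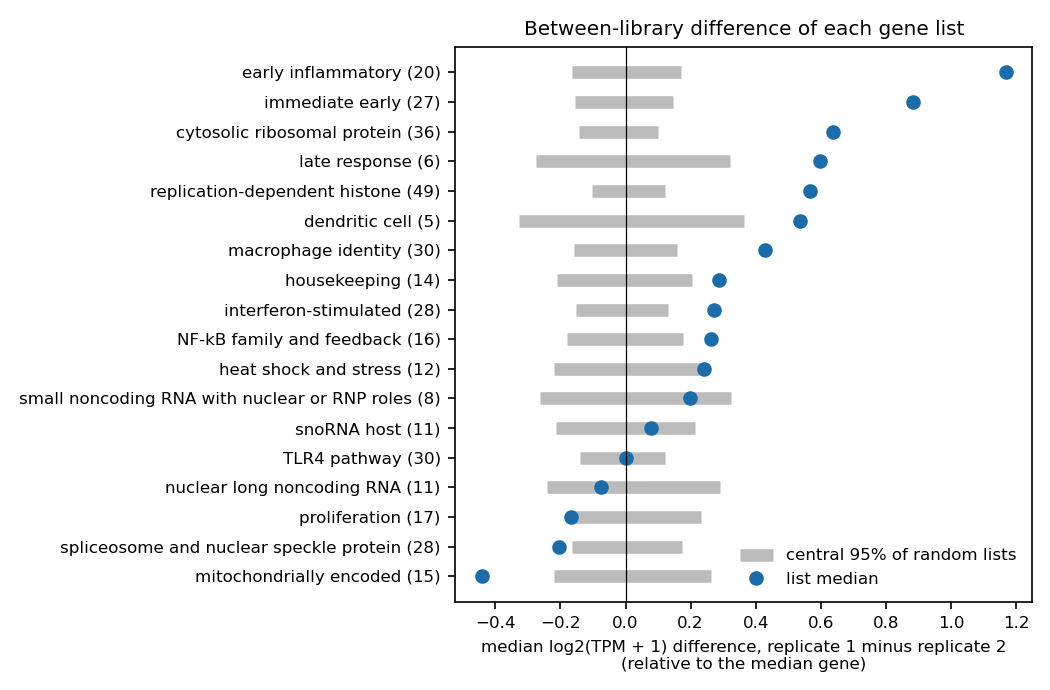
Median between-library difference of each gene list with at least 5 members, replicate 1 minus replicate 2, on the log2(TPM + 1) scale relative to the median gene (dots), with the central 95% of random lists matched on expression (grey bars) and the number of members in brackets. The early inflammatory list lies farthest to the right at 1.17 and the mitochondrial list farthest to the left at -0.44.

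Of 11653 genes with a mean of at least 50 counts, 248 were more than 2-fold apart between the libraries, 197 higher in replicate 1 and 51 higher in replicate 2. In the second quantification the split ran the other way, with 257 higher in replicate 1 and 812 higher in replicate 2, after TMM scaling of its own counts. It covered the 17956 genes that passed the filter on those counts, so the genes compared were not the same. The split was not computed over the genes that passed in both. Before centring, the median gene of the second quantification stood at -0.37 on the log2(TPM + 1) scale, a shift that does not enter this split. Most of the largest ratios belonged to genes that overlap other genes or are pseudogenes, and their values are uncertain. Zbed6, which lies in the same transcript as Zc3h11a, had 582 counts in replicate 1 and 0 in replicate 2, at least 117-fold higher when 3 counts stand for the 0. B430305J03Rik (164 against 0 counts), Gm49342 (107 against 0), Gm14288 (15.7-fold) and Snord22, which lies in Snhg1, were the others higher in replicate 1. Gm37376, on the strand opposite Malat1, had 0 counts in replicate 1 and 3948 in replicate 2. One of the genes annotated as Nnt, Gm5641 (7.31-fold), Gm15655 (7.11-fold), which is antisense to Maf, and Eif4a-ps4 (6.79-fold) were the others higher in replicate 2. Several of these ratios were smaller or absent by the second quantification, with Gm5641 at 25.8 and 34.1 TPM in replicates 1 and 2 and Gm37376 at 1589 and 3981 TPM. Gm49342 stood there at 5.28 and 1.94 TPM, Gm15655 at 10.2 and 29.0 TPM and B430305J03Rik at 0 in both. Others stayed far apart in the same direction, with Snord22 at 236 and 35.5 TPM and Zbed6 at 1.87 and 0 TPM. Likewise Gm14288 stood at 3.11 and 5.5e-05 TPM, the Nnt gene at 0.0956 and 2.43 TPM and Eif4a-ps4 at 0 and 7.80 TPM.

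Both quantifications of the same libraries were also set side by side. Among genes with a mean of at least 10 TPM, the pseudogenes of mitochondrial sequence Gm10222 (5935 TPM against 0) and Gm10925 (5155 against 0.289), and Gm28438, AC149090.1 and Rnu3a, were farthest lower in the second. Those farthest higher in it were Gm24924 (30.4 against 552 TPM), Gm22478, Pisd-ps1 (28.3 against 193 TPM), Gm26035 and Bud23 (16.7 against 101 TPM). In the gene tables Gm24924 had 0.02 and 6.64 counts in replicates 1 and 2, Gm22478 had 0 and 2, and Gm26035 had 47.1 and 1. Their means there are therefore uncertain.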

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

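The tests of cytoplasmic carry-over, of the opposite strand in its final form and of transcript length were chosen only after the result was seen. Counts were present on entries outside the annotated genes, above the limit of 3 counts that a count of 0 allows. The phiX entry held 228068 counts in replicate 1, 1.18% of its counts (95% Wilson interval 1.17 to 1.18%), and 47250 in replicate 2, 0.405% (0.401 to 0.409%). Entries with numeric identifiers held 32 and 37 counts in replicates 1 and 2.

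Early response mRNAs such as Egr1, Il1b and Tnf were higher in the replicate 1 library, with a median difference of 0.82 over 63 immediate early, NF-kB and early inflammatory genes. The pooled lists were unequal, at 0.88 for immediate early, 1.17 for early inflammatory and 0.26 for NF-kB genes. The ribosomal protein list stood at 0.64, above the NF-kB list alone, and the comparison with it below used the pooled genes. A bias from GC content and transcript length as the whole cause was argued against, since after regression on both over protein-coding genes the median residual was 0.75 and lay above all 10000 random lists, whose central 95% ran from -0.10 to 0.07. Carry-over of cytoplasmic RNA into replicate 1 cannot be told apart from other causes, because the early genes exceeded the ribosomal protein genes by 0.18 with a bootstrap interval from -0.04 to 0.47. Ribosomal protein mRNAs and Rn7s1 were also higher in replicate 1, as carry-over predicts. Of 15 mitochondrially encoded RNAs, 10 were lower there and 5 higher, which may depend on how reads shared with pseudogenes of mitochondrial sequence were assigned. On the TPM scale Malat1 (-0.71) and Neat1 (-0.34) were lower in replicate 1, while 5 of 11 nuclear long noncoding RNAs were higher. The effective length of Malat1 was 4287 nucleotides in replicate 1 and 2909 in replicate 2, and its log2 ratio of TMM-scaled counts was only -0.15. Neat1 had 194119 and 115713 expected counts in replicates 1 and 2, near the TMM library ratio of 1.66. Lower TPM of these 2 RNAs is therefore weak evidence of less nuclear RNA in replicate 1. The amount of input RNA differed with the library and stays open, and no biological explanation was tested, since both libraries belong to 1 group.

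A set of 466 protein-coding genes stood at 1 TPM or more in both libraries by the second quantification and under 0.1 TPM by the first, among them Thy1 (4.07 and 8.71 TPM in replicates 1 and 2), a fibroblast and stromal marker. The set also held olfactory and vomeronasal receptor genes and the Y-linked genes Uty (2.82 and 5.61 TPM) and Kdm5d (1.55 and 2.11 TPM), picked out after their values were seen. Uty and Kdm5d stood at 0 TPM by the first, where Xist stood at 329 TPM. A level in this set therefore need not mean expression. Reads from the opposite strand were argued against as the cause for most of them, since exons of 2.15% overlapped those of a gene at 1 TPM or more on the opposite strand (Wilson interval 1.17 to 3.90%), against 1.18% of 6034 control genes under 0.1 TPM by both (0.934 to 1.48%); the first form of this test, a difference from the controls, decided nothing because these intervals overlap, and the limit of 50% was set after the share was seen. Unspliced RNA of a spanning gene was argued against for most of them by a share of 6.65% (4.73 to 9.29%), which lay above the 2.85% of the controls (2.46 to 3.30%), so it may account for a small part. Short transcripts were argued against for most of the genes by a median length of 1652 nucleotides (1357 to 2020) over the transcripts that the second quantification ranks highest, a choice corrected after a first value was seen, but they stay open for the 41 genes under 300 nucleotides, which held 68.6% of the set's TPM there. Sequence shared with introns, repeats or unannotated RNA was not tested, and no biological explanation was tested.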

How the results depend on the processing

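Shares of counts, and shares of the same 10 genes, were chosen after seeing the data. Detected genes numbered 17703 at 0.1 TPM, 8073 at 5 TPM, 14526 at 10 counts, 17063 in the second quantification, 16977 with posterior mean TPM, 14830 after rescaling, and 13606 to 14097 in single libraries. Pearson's r was 0.88 with a pseudocount of 0.1, 0.98 without a filter and 0.92 with posterior mean TPM, and Spearman's rho was 0.94. The coefficient of variation was 0.177 without a filter, 0.147 at 100 counts, 0.0536 as the square root of the median of DESeq2 gene-wise dispersions and 0.231 in the second quantification. Genes more than 2-fold apart numbered 815 at a mean of 10 counts, 115 at 200 counts and 1069 in the second quantification. Of those in the second, 24.0% were higher in replicate 1 against 79.4% in the first, each after TMM scaling and over its own set of genes. The median gene of the second stood at -0.37 on the log2(TPM + 1) scale, which does not enter that split. In the second quantification the 10 genes highest there, 5 of them among the reported 10, held 62.6% of TPM, the reported 10 held 16.8%, mitochondrial genes 3.75%, protein-coding genes 21.4% and retained intron transcripts 4.82%. The reported 10 held 44.5% with posterior mean TPM and 17.4% of counts, and the 10 genes highest by counts, 4 of them among the reported 10, held 21.4% of counts. Protein-coding genes held 48.9% after rescaling and 77.0% of counts. Retained intron transcripts held 19.7% in protein-coding genes. Single libraries gave 46.8 to 48.1%, 5.61 to 7.03%, 29.5 to 31.0% and 5.92 to 6.13% for the 10 highest, mitochondrial, protein-coding and retained intron shares. Late response members detected were 12 at 0.1 TPM and 1 at 5 TPM. The number of members detected moved by more than 1.5 times, or from or to 0, for 8 of 26 lists at 0.1 TPM, 9 at 5 TPM and 3 in the second quantification (neutrophil, T and NK cell, fibroblast and stromal). Of 22 list differences, 18 kept their side of the random limits in the second quantification and 21 with each of the other settings. The macrophage identity difference was 0.175 and the interferon-stimulated one 0.181 in the second quantification, and the late response one 0.205 without a filter. In the second quantification the late response (0.26) and housekeeping (0.11) lists fell inside the limits and the small RNAs of ribonucleoproteins (0.82) rose above them. The heat shock list fell inside with a pseudocount of 0.1 (0.23), TMM-scaled counts (0.19) and the second quantification (0.0903). The dendritic cell list turned to -0.0815 without a filter. The cause was not tested. Single-gene TPM moved by more than the SD for 169 of 279 named genes in the second quantification. TPM is scaled to a fixed sum, of which genes at 0 counts in the gene tables, such as Gm23935 (112983 TPM) and Gm12896 (74360 TPM), take a large part there. Other genes are lowered by that scaling, so these moves and those of the shares are not gene-level disagreement alone. With 2 libraries, leaving 1 out always lies within the SD. Depth limits short genes, such as Hist1h2aj, whose 0 counts allow up to 1.03 and 1.47 TPM in replicates 1 and 2.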

Other observations

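The comparison of retained intron shares between gene lists was not among the results fixed at the start, and the test of annotated models was chosen only after the share of the spliceosome and speckle genes had been seen.

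Retained intron transcripts took unequal shares of the gene groups. In genes at a mean of 1 TPM or more with an annotated retained intron transcript, the median share of gene TPM held by such transcripts was 13.6% for 12 macrophage identity genes, 17.1% for 11 housekeeping genes and 20.7% for 29 ribosomal protein genes, each below the central 95% of random lists matched on expression. It was 61.3% for 5 snoRNA host genes and 54.0% for 9 immediate early genes, above that range. By the second quantification the macrophage (12.6%), housekeeping (16.4%), ribosomal protein (26.2%) and snoRNA host (63.6%) medians stayed outside the same limits, and the immediate early median (54.0%) lay at the 95.1st percentile, inside them. The TLR4 pathway (34.6%), NF-kB (31.3%) and early inflammatory (32.2%) medians lay near that of all 6544 genes (32.9%).

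Genes of spliceosome and nuclear speckle proteins, such as Ddx5 and Srsf5, had a high share as well. Their median share over 25 genes was 48.5%, above the central 95% of matched random lists (22.3 to 45.5%), and 49.8% by the second quantification (24.5 to 48.2%). A larger share of retained intron models in the annotation of these genes was argued against, since the median lay at the 99.8th percentile of random lists matched on the share of models that are retained intron. Whether intron-retaining transcripts of these genes are abundant cannot be told apart from reads of unspliced RNA assigned to such models, since intronic reads were not counted apart here.

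In the second quantification the highest entries, singled out after their values were seen, were Gm23935, Gm24245 and Gm24270, annotated as microRNA genes of 57 nucleotides with identical sequences. Each stood at 139315 TPM in replicate 1 and 86650 TPM in replicate 2, and each was listed at 0 counts in the gene tables. The pseudogenes Gm12895 and Gm12896 stood at 74360 TPM each in the second quantification and at 0 counts in the first.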
